A study of Mus musculus with 12 samples.

How the data were processed

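Adipose tissue was flash frozen at 6 months of age, RNA was isolated with TRIzol and chloroform followed by RNeasy columns, and libraries were made with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. The mice were of mixed C57BL/6 x 129/SvJ background. Samples were grouped by genotype and treatment as the labels give them, with 4 libraries labelled WT, 4 labelled Bbs2-/- and 4 labelled Bbs2-/- with the inhibitor.

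A table of estimated counts per gene for the 12 libraries was deposited by the authors, without scaling, as the differing column sums of 16317865 to 20224200 show. Between 92.96 and 94.17% of its values were whole numbers within 1e-06, so reads that fit several genes appear to have been shared between them. The second table deposited by the authors holds log2 FPKM values, with an upper quartile of 3.96 in every library, so the libraries were set to a common quartile. The lowest value was 0, so an offset was added before the log or low values were set to a floor. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and its annotation release are not given in the sources used here, so genes that overlap on opposite strands are uncertain, as are close paralogs. No column of values was left unused.

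The count table has 53431 gene identifiers, of which 52207 were found in the GENCODE mouse annotation on the same build, 51027 with the same version, and 1187 are miRNA hairpin identifiers. Symbols and coordinates were taken from that annotation. The log2 FPKM table has 18810 genes, of which 18556 are protein coding.

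Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group, and the robust quasi-likelihood test. All 12 libraries entered 1 fit with the group as its only term, and the 3 contrasts between groups were tested in it. P-values were adjusted by the Benjamini-Hochberg method over the 15968 genes left by the filter, with a threshold of 0.05. CPM values are counts per 1e6 counts of the TMM-scaled library size, and log2 CPM values for list tests have a prior count of 2. The common biological coefficient of variation was 0.29. Pairs of libraries of 1 group differed by a chi-square of 18.2 to 92.7 per degree of freedom, so none was a repeat of another within sampling noise.

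The 47 gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The lists were written by hand for the pathways that the series design names (sphingolipid, adipogenic and inflammatory), for metabolism, cilia, stress and RNA quality, and for cell types that adipose tissue or a neighbouring tissue could bring. Lists with at least 3 tested members, 46 in number, were tested against all other genes with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted with adjustment over all genes and over the list alone.

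Genes named in the text are Ugcg and the BBSome list, the 8 highest and 8 lowest log2 fold changes of each contrast, up to 4 list members with the smallest p, and the 10 genes with the largest changes in both contrasts with opposite signs. The highest and lowest genes had to pass the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, and predicted genes, pseudogenes and receptor segments were left out. Crisp1, Ptgds, Ddx3y and the 5 genes that rose in both contrasts were named after their values were seen. Single-gene results for some genes that this rule picks are not reported here, and these genes stay in the lists and in the counts of changed genes.

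On simulated counts for each contrast, with genes changed 1.5-fold, 2-fold and 4-fold, the procedure recovered 16.4, 56.7 and 86.4% of them for untreated Bbs2-/- against WT. For treated against untreated Bbs2-/- these shares were 26.9, 64.2 and 84.8%, and for treated Bbs2-/- against WT 11.9, 61.2 and 80.3%. These simulations changed 66 or 67 genes of each size, and where far more genes change, as in the first and second contrasts, the adjusted threshold is less strict and smaller changes pass.

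The alternatives were DESeq2 1.42.0, its size factors in edgeR, library size alone, other filters, fits of the compared groups only, limma-voom, limma-trend on the log2 FPKM values, 1 surrogate variable from sva 3.50.0, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library. Libraries WT 2 and WT 3 have library names of a single type where all others are merged, and a fit without them was run. That fit keeps WT 1 and WT 4, which hold ciliated epithelium RNA, so within WT the name type and that RNA cannot be told apart. After the data were seen, fits without mitochondrial genes, without 4 libraries holding ciliated epithelium RNA, and with the macrophage level as a covariate were added. Of the variance of the macrophage level 86.2% lies between the groups, so that fit removes much of the contrasts with untreated Bbs2-/- libraries. Calls lost in it do not separate macrophage content from group. Exact permutation tests over 4 against 4 libraries were two-sided and cannot give a p below 0.029.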

Results

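Messenger RNA of adipose tissue was sequenced from wild-type (WT) mice, from mice labelled as lacking both functional copies of Bbs2 (Bbs2-/-), and from Bbs2-/- mice given Genz667161 in the feed. Bbs2 encodes a subunit of the BBSome, a protein complex that moves membrane proteins in and out of primary cilia, and its loss in people causes Bardet-Biedl syndrome, in which obesity is common. Genz667161 is an inhibitor of glucosylceramide synthase, the enzyme encoded by Ugcg that makes glucosylceramide, the precursor of most glycosphingolipids. It was given at 0.033% of feed weight from 2 to 6 months of age. Each group had 4 libraries, and the 12 libraries held 16317865 to 20224200 estimated counts. The fat depot and the sex are not in the labels, and the Y-linked gene Ddx3y was at 87.6 ± 18.9, 95.9 ± 4.89 and 93.7 ± 12.6 counts per 1e6 (CPM; SD, n = 4) in WT, untreated and treated Bbs2-/- libraries. The labels number the samples of a group without saying that each is a separate mouse, so p-values measure the spread between these samples, which may be technical in part.

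Bbs2 (ENSMUSG00000031755.6, chromosome 8, 94067954 to 94098928, mm10) was measured first because it checks the labels. Its level was 12.5 ± 0.267 CPM (SD, n = 4) in the libraries labelled WT, 61.9 ± 9.41 in those labelled Bbs2-/- and 61.5 ± 5.3 in those labelled Bbs2-/- with inhibitor. The log2 fold change was 2.31 (SE 0.11, edgeR adjusted p = 1.62e-06) for untreated Bbs2-/- against WT and 2.30 (adjusted p = 1.7e-06) for treated Bbs2-/- against WT. The 8 libraries labelled Bbs2-/- lay between 53.7 and 70.6 CPM, and the 4 labelled WT between 12.1 and 12.7. Bbs2 counts were thus higher where the label says that functional Bbs2 is lost, which is not what a lost transcript would give. Libraries labelled Bbs2-/- and WT did not overlap, but the counts do not show which of them lack functional Bbs2. Every direction below is between libraries as labelled. A gene count does not show which part of the transcript was read, so counts from outside a deleted part would check nothing.

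Principal component 1 of log2 CPM, with 44.2% of the variance, placed the 4 untreated libraries labelled Bbs2-/- at 68.4 to 78.4 and the other 8 libraries at -3.8 or below. Some libraries held RNA of other tissues. The epididymis list summed to 1102 CPM in WT 1 and to at most 4.9 CPM in the other libraries. Foxj1, a transcription factor of ciliated epithelium, had 48, 164, 154 and 140 counts in WT 1, WT 4, treated 1 and treated 3 and at most 2 in the other libraries.

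**Figure D1:**
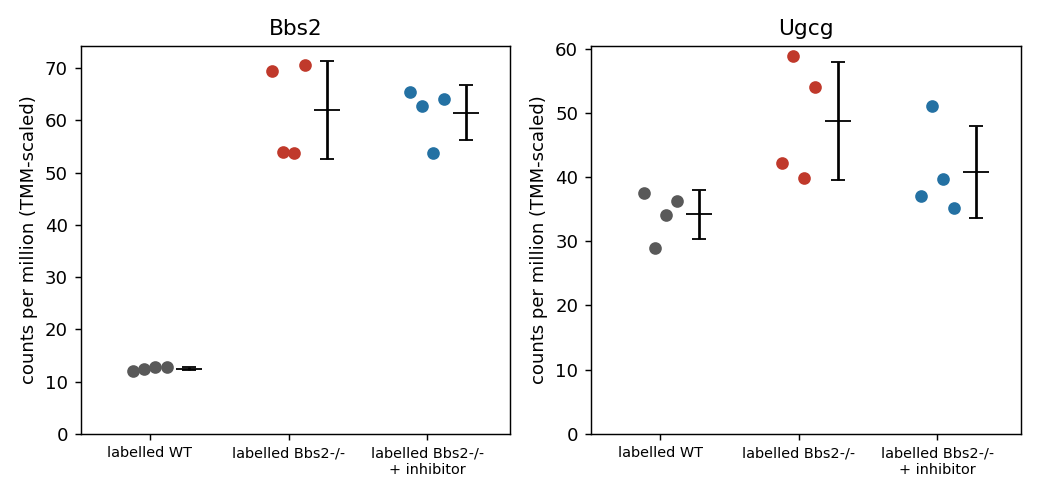
CPM (TMM-scaled, vertical axes from 0) of Bbs2 and Ugcg in the 4 libraries of each labelled group, 1 point per library, with the mean and SD beside them. Bbs2 lies between 12.1 and 12.7 in libraries labelled WT and between 53.7 and 70.6 in the 8 libraries labelled Bbs2-/-.

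In libraries labelled Bbs2-/- without inhibitor, genes of inflammation, macrophages, lysosomes and cell division were higher than in libraries labelled WT, and genes of mature adipocytes and of oxidative phosphorylation were lower. C1qa, a complement component made by macrophages, was 713 ± 155 CPM against 102 ± 26.8 (n = 4 in each group; log2 fold change 2.80, SE 0.25). Itgax, which encodes the integrin CD11c, was 576 ± 197 against 52.2 ± 36 CPM (log2 fold change 3.46, SE 0.64). Adipoq, which encodes adiponectin, was 1010 ± 28.8 against 4210 ± 913 CPM (log2 fold change -2.06, SE 0.22). Cyp2e1, a cytochrome P450, was 18.6 ± 9.59 against 1140 ± 278 CPM (log2 fold change -5.94, SE 0.63). The edgeR adjusted p was 3.53e-05 for C1qa, 0.00183 for Itgax, 8.24e-05 for Adipoq and 0.000105 for Cyp2e1.

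Of the 44 tested inflammatory mediators, 33 rose and 1 fell in libraries labelled Bbs2-/- (35 and 1 adjusted over the list alone), with a median log2 fold change of 1.5. The inflammasome genes Nlrp3 (log2 fold change 2.77, SE 0.28) and Casp1 (2.00, SE 0.24) and the receptor gene Tlr2 (2.15, SE 0.28) were among those that rose. Of 20 macrophage genes 16 rose (16 adjusted over the list alone), and the summed level of the list was 9762.7 ± 1373.9 CPM against 1745 ± 1102.4. Of 13 genes of lipid-associated macrophages 10 rose (10 adjusted over the list alone), among them Cd9 (2.04) and the lysosomal lipase gene Lipa (2.07). The camera adjusted p was 1.01e-09 for inflammatory mediators, 4.63e-08 for macrophage genes and 3.67e-05 for lipid-associated macrophage genes. It was adjusted p = 0.38 with an estimated correlation for each of these 3 lists. With the macrophage level as a covariate the lipid-associated macrophage list did not pass and its mean took the opposite sign (-0.559, camera adjusted p = 0.408). The mean of the inflammatory list was then -0.142, and camera still passed it as higher than other genes (adjusted p = 0.0308). Genes of several other immune cells rose as well: 9 of 10 MHC class II genes (9 adjusted over the list alone), 12 of 23 T and NK cell genes (16), 10 of 15 B and plasma cell genes (13) and 5 of 8 mast cell genes (5). Cd74, the invariant chain, had a log2 fold change of 1.51, Igkc 4.34 and Mcpt4 3.42 (2.574 without untreated Bbs2-/- 1, the highest library). Their camera adjusted p-values were 0.00127, 3.36e-05, 0.000118 and 0.0116, and with an estimated correlation the adjusted p was 0.45, 0.38, 0.38 and 0.44. The MHC class II list did not pass with the macrophage covariate. By contrast, 8 of 32 interferon response genes rose and 2 fell (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.142. Of 11 dendritic cell genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.985.

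Genes of sphingolipid metabolism that passed the test were mostly higher in libraries labelled Bbs2-/-. Ugcg (ENSMUSG00000028381.8, chromosome 4, 59189257 to 59222833) was 48.7 ± 9.2 CPM against 34.2 ± 3.79 in WT (n = 4 in each group; log2 fold change 0.51, SE 0.15, edgeR adjusted p = 0.0197). Of 40 tested sphingolipid core genes 16 rose and 5 fell (16 and 6 adjusted over the list alone), with a median log2 fold change of 0.25. S1pr2, a receptor of sphingosine 1-phosphate, had a log2 fold change of 2.30 (SE 0.24). Values were 1.59 for the ceramide kinase gene Cerk, 1.04 for the acid ceramidase gene Asah1 and 0.67 for Sptlc2, a subunit of serine palmitoyltransferase. Of 19 genes of glycosphingolipid and ganglioside metabolism 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.59. B4galt5 (2.30, SE 0.24) and B4galt6 (2.03, SE 0.34), which encode lactosylceramide synthases, and Hexa (1.38, SE 0.15), which encodes a lysosomal enzyme subunit, were among them. Of 29 lysosome genes 21 rose (21 adjusted over the list alone), with a median of 0.88, and the transcription factor genes Mitf (1.66) and Tfeb (1.19) were among them. The camera adjusted p was 0.0262 for the core list, 0.000224 for the glycosphingolipid list and 4.9e-08 for the lysosome list, and adjusted p = 0.38 with an estimated correlation for each. The macrophage list rose in the same libraries. Ugcg did not pass when WT 2 (0.44, edgeR adjusted p = 0.0596), Bbs2-/- 2 (0.44, adjusted p = 0.0521), WT 2 and WT 3 (0.41, adjusted p = 0.164) or the 4 libraries with Foxj1 counts (0.62, adjusted p = 0.0511) were left out, with the log2 FPKM values (0.39, limma adjusted p = 0.0718) or with the macrophage level as a covariate (0.14, adjusted p = 0.943). The core list did not pass camera in a fit of these 2 groups alone (adjusted p = 0.0646), with the log2 FPKM values (0.0844), without treated 4 (mean log2 fold change 0.33, adjusted p = 0.0537) or with the macrophage covariate (0.07, adjusted p = 0.201), and the glycosphingolipid list did not pass with that covariate (0.23, adjusted p = 0.265). Since the macrophage level lies mostly between the groups, losses with this covariate do not separate macrophage content from group.

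Adipocyte genes were lower in libraries labelled Bbs2-/-. Of 23 mature adipocyte genes 17 fell (19 adjusted over the list alone), with a median log2 fold change of -1.19, while macrophage genes rose, and their summed level was 41394 ± 3429.2 CPM against 82486.1 ± 9766.2. Cfd, which encodes adipsin, had a log2 fold change of -3.12 (SE 0.34), Retn, which encodes resistin, -3.76 (SE 0.29), and the glucose transporter gene Slc2a4 -1.64 (SE 0.17). Of 31 adipogenesis regulators 12 fell and 3 rose (12 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.12), while it passed fry (adjusted p = 0.0194) and passed camera on the log2 FPKM values (adjusted p = 0.0414). Ebf1 (-0.86), Rxra (-0.67) and Srebf1 (-0.56) fell, while Egr2 (2.73) and Cebpb (1.16), transcription factors of early adipogenesis that other cells also express, rose. Of 24 oxidative phosphorylation genes 22 fell (23 adjusted over the list alone; median -0.58), of 25 genes of lipolysis and fatty acid oxidation 17 fell and 1 rose (18 and 2), and of 20 genes of fatty acid synthesis 9 fell (10). Lipe, which encodes hormone-sensitive lipase, had a log2 fold change of -1.49 (SE 0.18), and the lipogenic gene Thrsp -2.14 (SE 0.28). The camera adjusted p was 9.85e-09 for mature adipocyte, 6.32e-08 for oxidative phosphorylation, 3.67e-05 for lipolysis and 0.00709 for fatty acid synthesis genes, and adjusted p = 0.38 with an estimated correlation for each of these 4 lists. The RNA of genes encoded in mitochondria was 3.35 to 4.46% of counts in the untreated libraries labelled Bbs2-/- and 5.19 to 9.39% in WT. Of these 13 genes 10 fell (11 adjusted over the list alone), in a list fixed beforehand for RNA quality. Nuclear copies of mitochondrial genes held a further 2.86 to 3.82% of counts in these untreated libraries and 4.25 to 7.7% in WT. Levels of single mitochondrial genes are therefore uncertain.

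Of 23 cell cycle genes 22 rose (23 adjusted over the list alone; median log2 fold change 1.49), for example Pcna (1.57, SE 0.17) and Mcm3 (1.24, SE 0.18). Of 34 extracellular matrix genes 18 rose and 1 fell (18 and 1 adjusted over the list alone), and Timp1 (3.29, SE 0.39), Lum (2.03) and Fn1 (1.89) were among those that rose. Cholesterol synthesis genes (12 rose and 1 fell of 23; 12 and 1 adjusted over the list alone) and genes of the unfolded protein response (10 rose and 1 fell of 19; 11 and 1) moved upward on balance, with Dhcr7 at 1.5, Sdf2l1 at 1.59 and Asns at -1.32. The camera adjusted p was 1.19e-08, 2.82e-05, 0.00493 and 0.00995 for these 4 lists, and adjusted p = 0.38 with an estimated correlation for each. Of 15 endothelial genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.25). Of 13 genes of the BBSome and its partners, Bbs2 and Bbs12 (0.70) rose, and Ttc8 (-0.88), Bbs1 (-0.47) and Bbs7 (-0.36) fell (3 rose and 4 fell adjusted over the list alone). The mean of this list was 0.00 and its sign depends on the scaling.

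Among all 15968 tested genes, 3124 rose and 3139 fell in libraries labelled Bbs2-/- at an edgeR adjusted p under 0.05, and 2590 of these 6263 genes differed at least 2-fold. Gpr50 (log2 fold change 5.99), Myh15 (5.44), Serpinb9b (4.67) and Cd72 (3.90) were among the genes with the highest changes, and Orm3 (-5.50), Rnase2a (-5.31), Acsm3 (-4.29) and the beta-3 adrenergic receptor gene Adrb3 (-3.99) among the lowest. Camera passed 22 of 46 lists, none of them with an estimated correlation, and fry passed 27. With library size in place of TMM scaling, 69.0% of the called genes were higher against 49.9%, and the median of all genes was 0.164 against -0.019. Without the WT libraries 2 and 3, whose library names are of another type found only in this group, 3417 genes were called, and 56 were called with the macrophage level as a covariate, of whose variance 86.2% lies between the groups. The WT libraries left in the first of these fits are those with Foxj1 counts, so it does not isolate the name type.

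**Figure D2:**
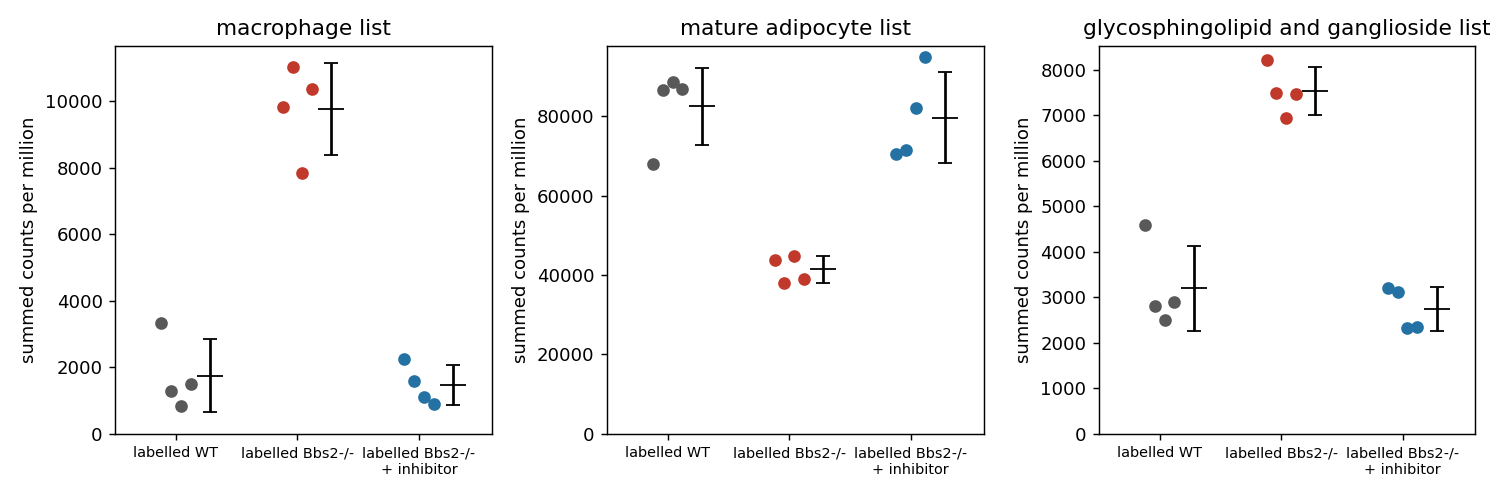
Summed CPM (vertical axes from 0) of the macrophage, mature adipocyte and glycosphingolipid lists in the 4 libraries of each labelled group, 1 point per library, with the mean and SD beside them. The macrophage list averages 1745 in WT, 9762.7 in untreated Bbs2-/- and 1463.7 in treated Bbs2-/- libraries.

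The comparison of treated with untreated libraries labelled Bbs2-/- asks which genes respond to the inhibitor. Macrophage, inflammatory, lysosome and cell cycle genes were lower with the inhibitor and adipocyte genes were higher. C1qa was 110 ± 31.8 CPM against 713 ± 155 (n = 4 in each group; log2 fold change -2.70, SE 0.25, edgeR adjusted p = 4.42e-05). Adipoq was 3230 ± 995 against 1010 ± 28.8 CPM (log2 fold change 1.68, SE 0.21, adjusted p = 0.000195), and Cyp2e1 was 1420 ± 922 against 18.6 ± 9.59 CPM (6.26, SE 0.64, adjusted p = 8.22e-05). Ugcg, the gene of the inhibited enzyme, was 40.7 ± 7.16 against 48.7 ± 9.2 CPM and did not pass (log2 fold change -0.26, SE 0.15, adjusted p = 0.203). Bbs2 differed by -0.01 (SE 0.11, adjusted p = 0.953).

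With the inhibitor, 15 of 40 sphingolipid core genes fell and 5 rose (15 and 6 adjusted over the list alone; median -0.24), and 11 of 19 glycosphingolipid genes fell and 1 rose (12 and 1; median -0.59). S1pr2 (-2.12), Cerk (-1.77), B4galt5 (-2.03) and Psap (-1.46), the gene of the saposins, fell. Of the inflammatory mediators 31 of 44 fell and 1 rose (33 and 1 adjusted over the list alone), with Nlrp3 at -2.50 and Ccl6 at -2.41. Of the macrophage genes 17 of 20 fell (17 adjusted over the list alone), of the lipid-associated macrophage genes 12 of 13 (13), of the lysosome genes 23 of 29 (25) and of the cell cycle genes 22 of 23 (23). Mmp12 had a log2 fold change of -4.34 (SE 0.70), Mitf -2.14 and Pcna -1.41. The camera adjusted p was 0.0227 for the core, 9.05e-05 for the glycosphingolipid, 5.74e-10 for the inflammatory, 5.55e-09 for the macrophage and 4.6e-07 for the lipid-associated macrophage list, and adjusted p = 0.35, 0.36, 0.35, 0.36 and 0.38 with an estimated correlation. For lysosome and cell cycle genes it was 4.2e-10 and 1.34e-08, and adjusted p = 0.35 and 0.43 with an estimated correlation. Without the 4 libraries with Foxj1 counts the core list did not pass camera (mean -0.44, adjusted p = 0.0568). With the macrophage covariate neither sphingolipid list nor the inflammatory list passed (adjusted p = 0.203, 0.175 and 0.175), and the mean of the inflammatory list was 0.262. The lipid-associated macrophage list did not pass with it either.

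Of 23 mature adipocyte genes 19 rose with the inhibitor (19 adjusted over the list alone; median 1.06), and of 31 adipogenesis regulators 20 rose and 2 fell (20 and 2; median 0.49). Retn (3.70, SE 0.29), Cfd (3.62, SE 0.34), Slc2a4 (1.73), Srebf1 (1.27), Rxra (0.95) and Ebf1 (0.94) rose, and Egr2 fell (-2.96). Of 24 oxidative phosphorylation genes 21 rose (22 adjusted over the list alone; median 0.48). The camera adjusted p was 6.05e-09, 0.00156 and 8.75e-07 for these 3 lists, and adjusted p = 0.36, 0.36 and 0.45 with an estimated correlation. With the macrophage covariate the adipogenesis list did not pass (mean 0.413 against 0.422, camera adjusted p = 0.146). The RNA of genes encoded in mitochondria was 5.62 to 8.44% of counts in treated libraries against 3.35 to 4.46% in untreated ones. Of these 13 genes 8 rose (8 adjusted over the list alone; camera adjusted p = 0.00355, adjusted p = 0.45 with an estimated correlation). Nuclear copies of mitochondrial genes held a further 4.78 to 7.0% of counts in treated and 2.86 to 3.82% in untreated libraries. Of 15 endothelial genes 8 rose (12 adjusted over the list alone), among them Cldn5 (1.22) and Kdr (1.0), and of 8 hedgehog signalling genes 6 rose and 1 fell (6 and 1), among them the receptor gene Ptch1 (0.77). Their camera adjusted p was 0.00313 and 0.0113, and adjusted p = 0.50 and 0.35 with an estimated correlation. In untreated Bbs2-/- against WT, 5 of the 8 hedgehog genes fell and 1 rose (5 and 1 adjusted over the list alone; median -0.66). The hedgehog list did not pass camera there (adjusted p = 0.122, adjusted p = 0.38 with an estimated correlation), while it passed fry (adjusted p = 0.000397). Extracellular matrix genes fell in 18 of 34 cases (19 adjusted over the list alone; camera adjusted p = 1.03e-06, adjusted p = 0.36 with an estimated correlation), and Mmp3 had a log2 fold change of -5.19. Among the BBSome genes, Ttc8 (0.73) and Bbs1 (0.56) rose, and Mkks (-0.41) and Bbip1 (-0.34) fell.

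Over all tested genes, 2947 rose and 3000 fell with the inhibitor at an edgeR adjusted p under 0.05, and 2473 of these 5947 differed at least 2-fold. Camera passed 28 of 46 lists, none of them with an estimated correlation, and fry passed 30. With library size in place of TMM scaling 35.5% of the called genes were higher, against 49.6%, and the median of all genes was -0.097 against 0.032. With the macrophage level as a covariate 2 genes were called. Of the variance of that level 86.2% lies between the groups, so this loss does not separate macrophage content from group.

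**Figure D3:**
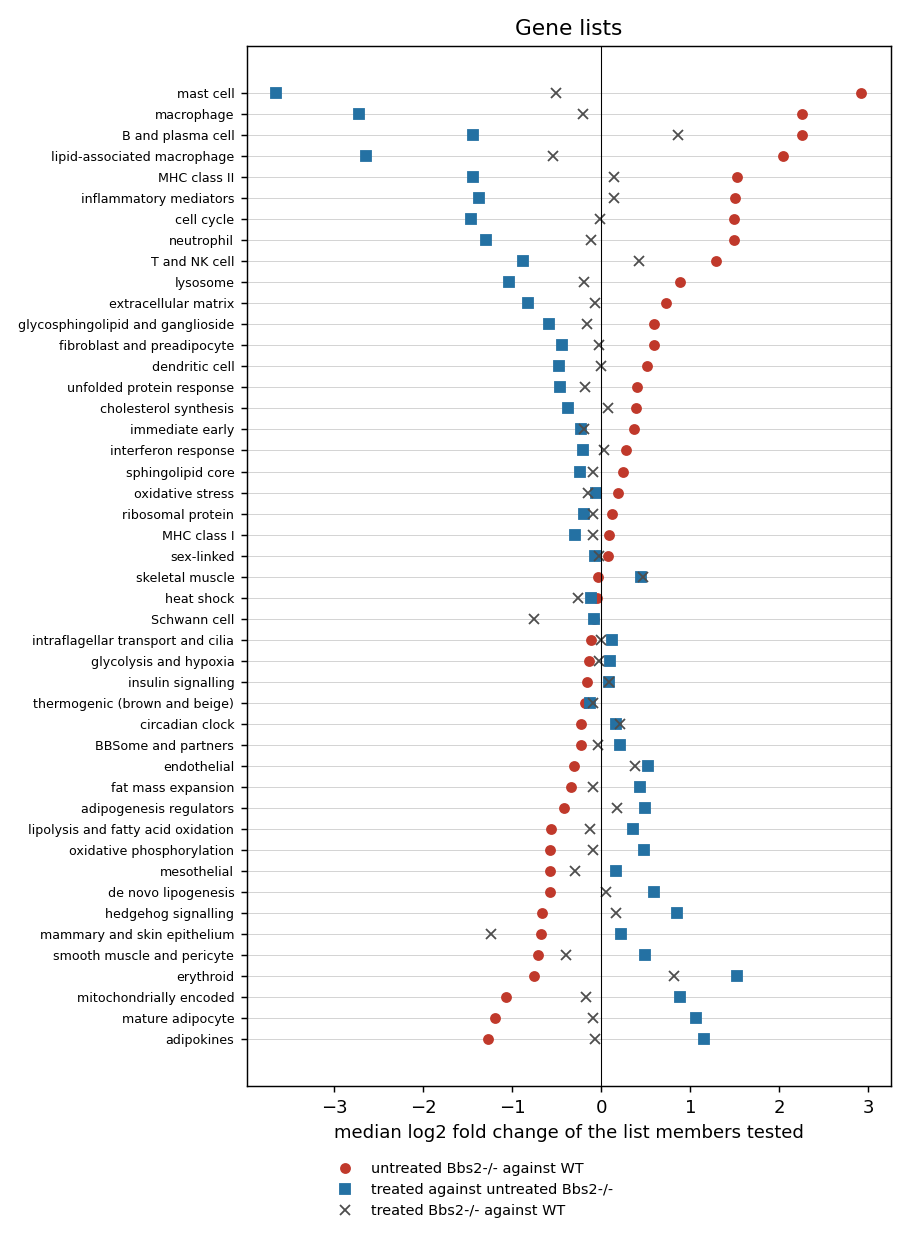
Median log2 fold change (horizontal axis) of the tested members of 46 gene lists in the 3 contrasts between labelled groups. Macrophage genes have a median of 2.25 in untreated Bbs2-/- against WT, -2.72 in treated against untreated and -0.21 in treated Bbs2-/- against WT, and mature adipocyte genes -1.19, 1.06 and -0.09.

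Genes that differed between libraries labelled Bbs2-/- and WT nearly all moved the other way with the inhibitor. Of the 6263 genes, 6179 (98.66%) had the opposite sign in treated against untreated libraries, and 4742 passed the test in both contrasts with opposite signs. The 3124 genes that rose had a median log2 fold change of 0.94 in untreated Bbs2-/- against WT and 0.03 in treated Bbs2-/- against WT (interquartile range -0.12 to 0.21). For the 3139 genes that fell these medians were -0.77 and -0.10 (-0.26 to 0.02). The 10 largest opposite changes were those of Cfap65, Ppp1r1b, Dcdc2a, Cuzd1, Dnah11, Foxj1, Adcy8, Esrp1, Cyp2e1 and Peak1os. The first 8 of these fell and then rose, with most of their counts in WT 1, WT 4, treated 1 and treated 3, the libraries with ciliated epithelium RNA. Cfap65, for example, had 106, 343, 331 and 396 counts there and at most 1 elsewhere. Cyp2e1 (-5.94, then 6.26) and Orm3 (-5.50, then 5.34), with counts in all libraries, fell and then rose, and Peak1os (5.87, then -6.02), Myh15 (5.44, then -5.53) and Serpinb9b (4.67, then -6.81) rose and then fell. Serpinb9b was 105 CPM in untreated Bbs2-/- 1 and at most 14.6 in the other 3, and without that library its values were 3.075 and -5.206, both past the test. Only 5 genes passed in both contrasts with the same sign. These rose in both and are named after their values were seen: Angptl8 (1.40, then 1.01), Dnajc6 (1.23, then 0.69), Wdr86 (1.05, then 0.92), Zbtb7c (0.36, then 0.45) and Mid1ip1 (0.32, then 0.48). Of the 6263, 22 still differed between treated libraries and WT at an edgeR adjusted p under 0.05.

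Both contrasts use the untreated libraries labelled Bbs2-/-, so an opposite sign is more frequent than not without any effect of the inhibitor. In 20 simulations with the Bbs2-/- change and no treatment change, 58.99% of changed genes on average, and at most 59.69%, had opposite signs, and at most 1 gene passed in both contrasts. When each contrast had its own 2 untreated libraries, in the 6 ways to split them, 97.22 to 99.11% had opposite signs and 2647 to 2842 genes passed in both. Independent lists of these sizes would share 587 genes that rose and then fell, and 2458 were observed. For genes that fell and then rose these numbers were 579 and 2284. The lists are not independent, since both contrasts use the untreated libraries, so this excess does not measure an effect of the inhibitor. Across genes, which are not independent replicates, the log2 differences of group means had a correlation of -0.91 and a covariance of -0.734, against -0.49 and -0.072 in 100 simulations with no change. The difference of covariances was -0.662. Both sets of simulations drew each gene separately, without variation common to many genes within a library. Without WT 2 and WT 3, 2938 genes passed in both contrasts with opposite signs. With the macrophage level as a covariate, which lies mostly between the groups, 2 did.

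**Figure D4:**
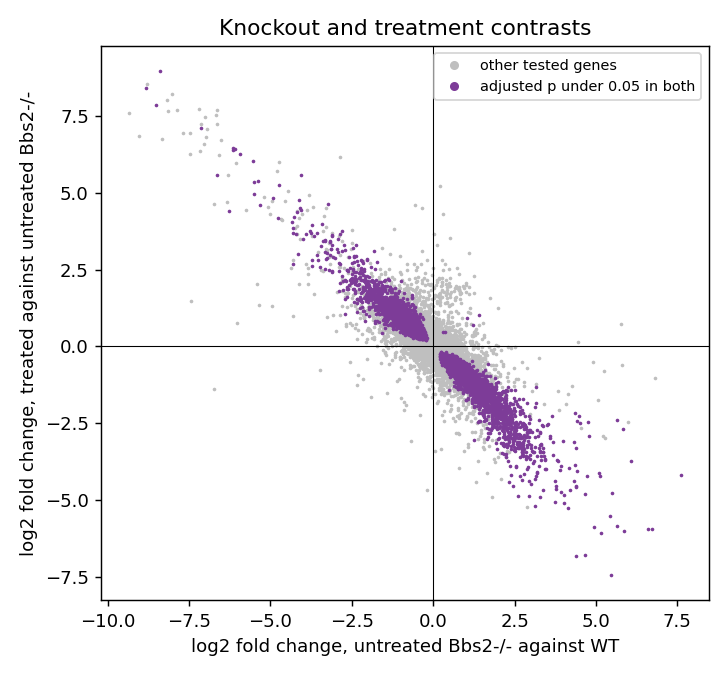
Log2 fold change of each of the 15968 tested genes in untreated Bbs2-/- against WT (horizontal axis) and in treated against untreated Bbs2-/- (vertical axis), libraries as labelled, with genes past an edgeR adjusted p of 0.05 in both contrasts in purple. Of the 6263 genes changed in the first contrast, 98.66% lie on the opposite side of 0 in the second.

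Treated libraries labelled Bbs2-/- differed from libraries labelled WT in 41 genes, 28 higher and 13 lower, with 1697 genes at an unadjusted p under 0.05. Bbs2 had an adjusted p of 1.7e-06. Angptl8, a secreted regulator of lipoprotein lipase, was 31.2 ± 15.5 CPM against 5.87 ± 1.03 (n = 4 in each group; log2 fold change 2.41, SE 0.34, edgeR adjusted p = 0.0199), and Dnajc6 was 16.7 ± 3.54 against 4.42 ± 1.23 (1.92, SE 0.22, adjusted p = 0.00721). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 41.3 ± 12.3 against 135 ± 40.1 CPM (-1.71, SE 0.26, adjusted p = 0.0284). Srebf1, a transcription factor of fatty acid synthesis, was 368 ± 72 against 225 ± 19.9 CPM (0.71, SE 0.13, adjusted p = 0.0477). Other genes that passed were Serpina3b (2.62), Adamtsl2 (2.12), Axin2 (1.58), Oxtr (1.47) and Zfp467 (0.81), which rose, and Net1 (-1.65), Bcat1 (-1.33), Grb14 (-1.30) and Jade3 (-1.13), which fell. Without WT 2, only 3 of the 41 genes (7.3%) still passed, namely Bbs2, Dnajc6 and Jade3, and all 41 kept their sign.

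None of the 44 inflammatory mediators, 20 macrophage, 29 lysosome, 40 sphingolipid core, 19 glycosphingolipid, 23 mature adipocyte or 24 oxidative phosphorylation genes passed the edgeR test in treated Bbs2-/- against WT. Adjusted over the list alone, 1 macrophage gene was higher and 1 lysosome gene lower, and 0 genes passed in the other 5 lists. At an unadjusted p under 0.05 the edgeR counts were 11, 2, 9, 4, 2, 5 and 0 in that order of lists, and DESeq2 called 1, 1, 1, 1, 0, 1 and 0. Of all tested genes 10.6% had such an unadjusted edgeR p. The inflammatory (11 of 44), lysosome (9 of 29) and mature adipocyte (5 of 23) lists lay above that share, and the others did not. Small remaining differences from WT in those lists thus stay open. Of the adipogenesis regulators Zfp467 and Srebf1 rose (3 adjusted over the list alone; camera adjusted p = 0.000598, adjusted p = 0.63 with an estimated correlation). Endothelial genes had a median of 0.38 with 0 of 15 past the edgeR test (0 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 with DESeq2; camera adjusted p = 0.000598, adjusted p = 0.96 with an estimated correlation). Ugcg differed by 0.25 (SE 0.15, adjusted p = 0.596). Of the 41 genes, 22 had also passed in untreated Bbs2-/- against WT and 19 had not. Lysosome genes had a mean of -0.18 (camera adjusted p = 0.00833, adjusted p = 0.96 with an estimated correlation, exact permutation p = 0.257), and the lipid-associated macrophage genes a mean of -0.87 (median -0.54, camera adjusted p = 0.0147, adjusted p = 0.96 with an estimated correlation, exact permutation p = 0.371). The summed level of the latter list was 4629 CPM in WT 1, 1489.7 to 2159.8 in the other libraries labelled WT and 1069.5 to 2502.4 in the treated ones, so WT 1 carries much of that difference. Of these 13 genes 0 passed edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 with DESeq2). Camera passed 11 of 46 lists, none of them with an estimated correlation, and fry passed 0. The other lists that camera passed were cholesterol synthesis, B and plasma cell, erythroid and hedgehog genes as higher, and lipolysis, thermogenic and ribosomal protein genes as lower. The count was 275 with DESeq2, 2 in a fit of these 2 groups alone, 1 without WT 2 and WT 3, and 2 without the 4 libraries with Foxj1 counts. Leaving out 1 library gave 3 genes without WT 2, 8 without WT 3, 14 without WT 4, 21 without untreated Bbs2-/- 2, 19 without 3, 17 without 4, and 12 and 10 without treated 1 and 2.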

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

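The tests of explanations and the counts over other splits of the libraries in this part were chosen after the results were seen, whereas the measure for single libraries that stand apart was fixed beforehand.

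Bbs2 was higher in the libraries labelled Bbs2-/- than in those labelled WT, against what a lost transcript would give. The lowest of the 8 libraries labelled Bbs2-/- was 4.21 times the highest labelled WT, which argues against single wrong labels and against a swap of some libraries, but not against an exchange of the genotype labels as a whole. A strain difference of the region remains open, since 17.2% of the 64 tested genes within 5 Mb (exact 95% interval 8.9 to 28.7%) had an unadjusted p under 0.05 in treated Bbs2-/- against WT, against 10.6% of other genes (Fisher's exact test, two-sided p = 0.1). Reads from a part of Bbs2 outside the deletion could give counts in these libraries, but would not by themselves give a 4.93-fold higher mean. Whether a partial or a whole transcript was raised cannot be told without counts per exon. A biological effect of the genotype on its own transcript was not tested.

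Nearly all genes that differed in untreated Bbs2-/- libraries moved the other way with the inhibitor. When each contrast had its own untreated libraries, 97.22% or more of the genes still had opposite signs. The highest simulation without treatment change gave 59.69%, which argues against shared sampling noise of separate genes alone. Variation common to many genes within a library was not in these simulations. A feature common to all untreated libraries would stay in both contrasts when the untreated libraries are split, and was not tested. Scaling is argued against as well, with 98.62% under library size alone. The part of the change left in treated libraries had a median of 9.2% (quartiles -8.9 and 29.8%). This argues against most of the change remaining below the reach of the test. Smaller remaining changes stay open. For treated Bbs2-/- against WT the procedure recovered 11.9% of simulated 1.5-fold changes. In the data, 10.6% of tested genes had an unadjusted edgeR p under 0.05 there. An effect of the inhibitor and a feature common to the untreated libraries both stay as hypotheses.

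Immune and lysosome lists were higher and adipocyte lists lower in untreated Bbs2-/- libraries. A lower share of adipocyte RNA with all other cell types in proportion would raise macrophage and endothelial genes alike. The change of the macrophage list mean exceeded that of the endothelial list by 2.48 log2 units (SD 0.35 in untreated Bbs2-/- and 0.98 in WT, exact permutation p = 0.029, the smallest that 4 against 4 libraries can give), which argues against it as the whole cause. More macrophages, or more RNA per macrophage, stay open as hypotheses, since no cell counts are at hand. The inhibitor and the genotype are the biological differences that the design names, and neither was tested apart from the labels.

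The 8 libraries of a contrast were split into 4 and 4 in 35 ways, fitted with the compared groups only. For untreated Bbs2-/- against WT the real split called 5934 genes and was the only 1 with so many, the highest other calling 2. For treated against untreated Bbs2-/- the real split called 6261 genes and was again the only 1, the highest other calling 0. A share of 1 in 35 is the smallest that these splits can give. Splits that mix differing groups also have a wider spread within each part, which lowers their counts. Chance is therefore not excluded in these contrasts. For treated Bbs2-/- against WT the real split called 2 genes, 4 splits called as many, and the highest other called 92, so chance cannot be excluded. That other split puts WT 1, WT 4, treated 1 and treated 3 together, the libraries with Foxj1 counts, and points to a structure of the samples. For the number of lists passed by camera chance cannot be excluded in any contrast: 7 splits reached the real 20 in untreated Bbs2-/- against WT (highest other 27), 2 reached the real 26 in treated against untreated (highest other 26), and 15 reached the real 13 in treated Bbs2-/- against WT (highest other 18).

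A library stood apart from the other 3 of its group in 36 of 485 groups of 4 values, or 7.4%. Chance gives about 1 in 20 for normally spread values, which low counts are not. Crisp1 and Ptgds, which are among the 36, were named after their values were seen. The share therefore does not measure an excess over chance. Untreated Bbs2-/- 1 held 8 of these and WT 1 held 7. In 7 of the 36 a library had 1 or 2 counts where the other 3 had 0, which says nothing of that library: Cfap65 and Esrp1 (0.0472 CPM each) and Cuzd1 (0.0944) in untreated Bbs2-/- 4, Dcdc2a (0.0494) in untreated 2, Adcy8 (0.0515) in untreated 1, and Peak1os in WT 3 (0.0663) and treated 3 (0.0529).

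In WT 1, Crisp1, an epididymis gene, was 1080 CPM against at most 0.291 in the other WT libraries, and the epididymis list summed to 1100 CPM against at most 4.9. Its S1pr2 (13.6 CPM), Cerk (64.6) and cell cycle list (317) were above those of the other WT libraries, its mammary and skin epithelium list (24) as well, and its mature adipocyte list (67900) below. In WT 2, Mkks (25.4 CPM), Srebf1 (254) and Grb14 (69.1) were higher than in the other WT libraries. Ptgds was 169 CPM in WT 3 against at most 4.71, and Mmp3 was 4.65 CPM in WT 4 against at most 1.28.

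In untreated Bbs2-/- 1, Serpinb9b (105 CPM against at most 14.6), Clec4d (90.4 against at most 27.4), Mcpt4 (42.4 against at most 12.8) and Gusb (358 against at most 294) were higher than in the other 3 libraries. Its mast cell list (199 CPM), oxidative stress list (5740) and glycolysis and hypoxia list (5690) were also the highest. In untreated Bbs2-/- 3, Maf (111 CPM) was lower and Rxra (126) higher than in the others, and in untreated Bbs2-/- 4 Bbs12 (6.99) was higher and Retn (60.5) lower.

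In treated 3, Igkc (101 CPM against at most 13.3) and Jchain (19.5 against at most 3.1) were higher, and the ribosomal protein list (10200) was lower than in the other treated libraries. Gpr50 was 22.7 CPM in treated 2 against at most 3.21. In treated 4, Slc2a4 (225 CPM) and the total count (20.2 in units of 1e6) were higher.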

How the results depend on the processing

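The fits without mitochondrial genes, without the 4 libraries with Foxj1 counts and with the macrophage covariate were chosen after the data were seen, the others before. With DESeq2, its size factors, library size alone, other filters, limma-voom, 1 surrogate variable and no mitochondrial genes, the counts for untreated Bbs2-/- against WT and for treated against untreated Bbs2-/- stayed within 1.5 times (5430 to 6921 and 5200 to 6546), and 98.62% of changed genes still had opposite signs with library size alone. The Xist covariate was not run, because Xist did not pass the filter and the Y-linked genes did not separate the libraries. Except where the construction shows it (fewer libraries, or a larger change required), the cause of the shifts below was not tested.

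Treated Bbs2-/- against WT had 275 genes with DESeq2, 2 with the compared groups only, 24 with log2 FPKM (27 with a mean above 0), 21 with a log2 fold change of at least 1, 1 without WT 2 and WT 3, 2 without the 4 libraries with Foxj1 counts, 67 with the macrophage covariate, and 3 to 49 leaving out 1 library. With a log2 fold change of at least 1, 2590 and 2473 genes were called in the other contrasts and 1908 in both with opposite signs, and Ugcg (0.510) no longer passed. Without WT 2 and WT 3, untreated Bbs2-/- against WT had 3417 genes and 2938 passed in both.

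The replicate block gave 6012, 5680 and 9 genes in the 3 contrasts, and moved only the last by over 1.5 times. The labels do not say that the numbers pair the samples. Of 12 same-numbered pairs, 4 had a correlation of deviations above 0.1 (median 0.016, against -0.0105 for other pairs), and 0 libraries correlated best with their own number in both other groups. In treated against untreated Bbs2-/- all 4 same-numbered pairs were positive (0.1 to 0.308), 6 of 8 libraries correlated best with their own number, and the mean of 0.167 was the highest of the 24 ways to match the libraries, a count made after the values were seen. This is a hint of pairing in that contrast, from the data and not the design. In untreated and treated Bbs2-/- against WT, 14 and 13 of the 24 ways gave as high a mean.

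Ugcg in untreated Bbs2-/- against WT no longer passed with log2 FPKM (0.387 with either filter), without WT 2 and WT 3 (0.413), without the 4 libraries with Foxj1 counts (0.617) or with the macrophage covariate (0.137), and ranged from 0.438 to 0.626 leaving out 1 library. Bbs2 in treated against untreated Bbs2-/- was 0.052 with log2 FPKM (either filter), 0.002 without WT 2 and WT 3, 0.051 without the 4 libraries with Foxj1 counts, 0.105 with the covariate, and -0.095 to 0.049 leaving out 1 library, and did not pass in any.

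The sphingolipid core list in untreated Bbs2-/- against WT was not called with the compared groups only (mean 0.334) or with log2 FPKM (0.194 with either filter), and ranged from 0.295 to 0.456 leaving out 1 library. In treated against untreated Bbs2-/- it was not called without the 4 libraries with Foxj1 counts (-0.436). The adipogenesis list passed in untreated Bbs2-/- against WT with log2 FPKM (-0.220 with either filter) and with fry (-0.284). With an estimated correlation, no list was called: in untreated Bbs2-/- against WT the means were 0.358 for sphingolipid core, 0.862 for glycosphingolipid, -1.460 for mature adipocyte, 1.398 for inflammatory and 2.026 for macrophage genes, and in treated against untreated -0.428, -0.907, 1.369, -1.465 and -2.330, with 0.422 for adipogenesis.

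With the macrophage covariate, of whose variance 86.2% lies between the groups, 56 genes were called in untreated Bbs2-/- against WT, 2 in treated against untreated and 2 in both. The sphingolipid core (0.069), glycosphingolipid (0.232), lipid-associated macrophage (-0.559) and MHC class II lists were not called in the first contrast. Nor were sphingolipid core (-0.076), glycosphingolipid (-0.217), adipogenesis (0.413), inflammatory (0.262), MHC class II (0.126) and lipid-associated macrophage (0.060) in the second, where Ugcg was 0.144. Relative to all other genes, which is what camera tests, the lipid-associated macrophage list took the opposite direction in the first contrast and the MHC class II list in the second. The mean log2 fold change also took the opposite sign for the inflammatory list in both contrasts, in the first at -0.142 with camera still passing it as higher than other genes (adjusted p = 0.0308), and for the lipid-associated macrophage list in the second (0.060). Single genes took the opposite sign without passing the test. In untreated Bbs2-/- against WT these were Ndufb8 (0.018), Clec7a (-0.020), Elane (0.354), Robo4 (0.282), Tnni2 (-0.226), Ift43 (0.021), Cat (0.013), Hspd1 (0.145), Nr1d1 (0.058) and Rpl41 (0.137). In treated against untreated they included Rnf128 (0.313), Mlxipl (-0.205), Mgll (-0.117), Acads (-0.135), Fabp3 (0.245), Ebf2 (-0.011), Ndufs3 (-0.063), Ndufb8 (-0.174), Ncr1 (1.127), Irf8 (0.566), Kcnj8 (-0.204), Tnni2 (0.999), Ift46 (-0.010), Ift43 (-0.285), Mcm5 (0.078), Birc5 (0.008), Nr1d1 (-0.568), Tef (-0.270), mt-Cytb (-0.080) and mt-Nd4 (-0.126).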

Other observations

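The relation tested in this part was written down before its result was seen, although the lists it joins had been seen to move together between the groups.

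Erythroid genes rose with the inhibitor in 4 of 5 cases against untreated Bbs2-/- libraries (5 adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.45 with an estimated correlation). Hba-a1, a hemoglobin gene, was 535 ± 219 CPM against 171 ± 63.9 (SD, n = 4 in each group; log2 fold change 1.64, SE 0.45, edgeR adjusted p = 0.0145) and 290 ± 161 CPM in WT. Ucp1, the uncoupling protein of brown fat, was 0.0654 ± 0.0501 CPM in treated libraries, 1.88 ± 1.66 in untreated Bbs2-/- and 2.12 ± 0.975 in WT. Its counts were 0 to 2 in treated libraries, near the lower end of what these depths can show, 8 to 76 in untreated ones and 16 to 56 in WT. In treated Bbs2-/- against WT its log2 fold change was -4.88 (SE 0.88, edgeR adjusted p = 0.0485). Ucp1 was not among the genes that still passed there without WT 2. Of 10 smooth muscle and pericyte genes 5 fell and 1 rose in untreated Bbs2-/- against WT (5 and 1 adjusted over the list alone; camera adjusted p = 0.142). Their summed level was 2205.8 CPM in WT 1, the library with epididymis RNA, and 962.8 to 1189.9 in the other WT libraries. In untreated Bbs2-/- libraries it was 632.4 to 1056.7 CPM.

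One hypothesis is that the sphingolipid lists follow the macrophage RNA content of a library. It was tested over the 8 WT and treated libraries, which leave out the untreated Bbs2-/- group, with 2 relations computed. The glycosphingolipid list mean correlated with the macrophage list mean at r = 0.92 (exact permutation p = 0.0012, adjusted p = 0.0025; Spearman rho 0.9, exact p = 0.0046), and at r = 0.83 (exact p = 0.042) without WT 1 and WT 3, the libraries farthest from the median. The sphingolipid core list gave r = 0.87 (exact permutation p = 0.0055, adjusted p = 0.0055; rho 0.79, exact p = 0.028) and r = 0.53 (exact p = 0.29) without those 2, so that relation rests on them. Within the 6 libraries with merged-type names r was 0.93 (exact p = 0.0083) for the glycosphingolipid and 0.83 (exact p = 0.044) for the core list, and the other 2 are too few for a value. WT 1, the library with epididymis RNA, is among the 6 with merged-type names. No other list was set against these means, so r does not separate macrophage content from other shares of tissue RNA that vary with it. Lysosomal genes such as Psap are abundant in macrophages. A higher macrophage content stays a hypothesis for part of the glycosphingolipid list's difference between the groups. Whether adipocytes themselves change these genes cannot be seen in RNA of whole tissue.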
